A study of Danio rerio with 8 samples.

How the data were processed

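Total RNA from 8 zebrafish melanomas was labelled with Cy3 by the array maker and hybridised to 1-colour oligonucleotide arrays, 1 tumour per array, per the labels' protocols. The labels call the 4 samples of each group separate biological replicates from distinct tumours. The deposited probe files hold the scanner intensity of each perfect-match probe on a linear scale, quantified with NimbleScan 2.4.67 on a zebrafish expression design named after the Zv7 assembly, per the file headers. Each array carried 389307 probes, 4307 of them with random sequence, and the mismatch column held no value above 0 and was not used. The other probes are grouped into 37157 target sequences, 21894 of which have 12 probes and 1026 fewer than 4. No background correction, normalization or summary had been applied to these intensities. The deposited value table of the series holds 1 linear intensity per target sequence and array. The submitters' processing notes name RMA, with no role. On the log2 scale the table correlated across target sequences with values computed here at offset 0, for each array at r = 0.995 or 0.996, and no array's column correlated above 0.96 with another array, so its columns follow their labels. Its medians were 431, 402, 429 and 437 for MiniCoopR-GFP replicates 1 to 4 and 405, 436, 417 and 415 for MiniCoopR-SETDB1 replicates 1 to 4, and any step after RMA, such as centring, is not given in the sources used here. It served only as an alternative.

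From the probe intensities, background was corrected per array with limma 3.58.1 in R 4.3.3 (normexp, offset 50, fitted on all probes). Values were quantile normalized between the 8 arrays, taken to log2 and summarised per target sequence by median polish with at most 10 iterations, without the random probes. All 37157 target sequences were tested with lmFit and eBayes on all 8 arrays, with no filter on dim sequences and no covariate, and p-values were adjusted after Benjamini and Hochberg with a threshold of 0.05. Errors of log2 differences are limma's moderated standard errors, and adjusted p-values of single genes are limma's. A target sequence was counted as above the random probes on an array when its value exceeded their 95th percentile. Where no array of a group was above it, the change is given as "at least N-fold": the mean of the brighter group against the dim group's mean of, per array, the higher of its own value and the lowest target above the random probes. The number of arrays limits the precision. Exact permutation tests were two-sided over the 70 assignments of the 8 arrays to 2 groups of 4, so the smallest p they can give is 0.0286.

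The files identify target sequences by accessions and do not pair them with gene symbols. Of 3055 RefSeq accessions, 2663 matched exactly 1 gene of the given table for assembly GRCz12tu, which was used for names only, and gave 2650 symbols. These are 7.17% of all target sequences. The other sequences, among them 10153 Ensembl and 11285 Vega transcripts, stay unnamed here, and no coordinates were used. For 13 symbols with 2 or more target sequences the one with the highest mean over all arrays was taken. For 2 of these symbols the target sequences differed in sign.

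The design, the alternatives, 23 gene lists and the rule for named genes were fixed before the data were examined. The rule took the setdb1 genes; up to 12 genes per direction past the threshold whose groups did not overlap, filled to 6 with the lowest p-values of other genes without overlap where fewer passed; and the 2 members of each list with the largest moderated t, or up to 6 for HOX genes. Not every gene that the rule takes is reported here. The lists covered HOX cluster, non-HOX homeobox, melanocyte pigment, neural crest and early pigment progenitor, cell cycle, p53 pathway and senescence, MAPK output, H3K9 and chromatin machinery, Wnt pathway targets, interferon and antigen presentation, stress and immediate early, ribosomal protein and oxidative phosphorylation genes. Markers of xanthophore and iridophore, epidermis, skeletal muscle, myeloid, lymphocyte, erythrocyte, endothelial, fibroblast and matrix, nerve and glia, and bone and cartilage cells were included because a dorsal tumour could hold them. The HOX list was chosen knowing that the study of these samples speaks of HOX genes and is not independent evidence. The 22 lists with at least 3 measured members were tested with camera (preset correlation 0.01) over the 2650 symbols, adjusted over the lists, and again with an estimated correlation and with fry, which asks whether a list's genes move one way without comparing them with other genes.

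On simulated data with the arrays' own spread, limma over 37157 target sequences recovered 14.9% of 2-fold and 62.9% of 4-fold changes with a mean of 4.6 false calls in 10 runs. Camera over 2650 symbols made 0 calls in 20 runs without a change and recovered a 2-fold shift of the 18 muscle genes in 100% of runs. These runs drew every gene independently. In the real data the estimated correlation was 0.367 for the skeletal muscle and 0.821 for the cell cycle list. The runs therefore cannot show how often camera calls unchanged lists whose members vary together. The processing from probes on, run once on 12000 simulated target sequences, recovered 62.5% of 4-fold changes with 8 false calls, and fitted changes were 0.897 of those simulated. Unchanged sequences of that run had a median SD of 0.248 over the 4 arrays of MiniCoopR-SETDB1, against a median SD of 0.386 pooled within both groups in the real data, so that run was less noisy and its recovery is optimistic.

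Alternatives were the background correction, the scaling between arrays, the probe summary, the deposited value table, a filter on dim sequences, the variance model, array weights, other thresholds, gene symbols as the unit counted, each array left out, the replicate number as a block, and the chip series. By the first 3 digits of the chip numbers in the sample titles, 5 arrays (3 MiniCoopR-GFP, 2 MiniCoopR-SETDB1) form a main series. The 3 others (1 and 2) do not all share these digits with one another and were pooled. This division served as a block and as separate sets. The labels do not say whether chip numbers mark batches. Per the file headers MiniCoopR-SETDB1 replicate 3 was quantified on a later day than the other 7 arrays, and leaving it out is among the alternatives. Reprocessing without MiniCoopR-SETDB1 replicate 2 and the level of the random probes as a covariate were added after seeing the data, as were 18 further gene lists, 16 of which had at least 3 measured members.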

Results

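Gene expression was measured in 8 melanomas of adult zebrafish. The fish carried a loss-of-function p53 mutation, a mitf mutation that leaves them without melanocytes of their own, and an activated BRAF transgene under the mitf promoter. MiniCoopR is a transposon vector that restores melanocytes in such fish and delivers a second gene to them. For 4 of the tumours it delivered SETDB1, a histone H3 lysine methyltransferase, and for 4 control tumours GFP. Dorsal tumours grew for 3 weeks from onset. The comparison asks which transcripts differ between melanomas that arose with SETDB1 and with GFP. The median raw probe intensity was 608 ± 37.2 (SD, n = 4) in MiniCoopR-GFP and 666 ± 109 (SD, n = 4) in MiniCoopR-SETDB1, which overlapped between the groups. The median of the random probes, a measure of array background, was 260 ± 50.6 (SD, n = 4) in MiniCoopR-GFP and 188 ± 11.3 (SD, n = 4) in MiniCoopR-SETDB1. All 4 control arrays lay above all 4 others (exact permutation test, two-sided p = 0.0286, the smallest possible). The slope of the signal along the target sequences, which RNA quality can change, was 0.436 ± 0.0960 (SD, n = 4) in MiniCoopR-GFP and 0.575 ± 0.0816 in MiniCoopR-SETDB1, and the median probe residual 0.174 ± 0.0406 and 0.129 ± 0.0134 (exact permutation p = 0.0571 for each, two-sided). The share of target sequences above the random probes was 68.3% ± 5.34 (SD, n = 4) and 73.7% ± 3.5 (SD, n = 4).

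Among genes with a symbol, 1 was higher and 2 were lower in MiniCoopR-SETDB1 melanomas past the threshold. The transcript of met, the receptor tyrosine kinase for hepatocyte growth factor, was 3.36-fold lower, with a log2 difference of -1.75 ± 0.25 (SE, n = 4 per group, limma adjusted p = 0.0494). The transcript of enpp4, a membrane nucleotide phosphodiesterase, was 2.84-fold lower, at -1.51 ± 0.18 (SE, n = 4 per group, limma adjusted p = 0.0440). The transcript of pank1a, a pantothenate kinase that starts coenzyme A synthesis, was at least 1.64-fold higher (limma adjusted p = 0.0473). Its mean log2 intensity was 8.44 in MiniCoopR-SETDB1 and 6.69 in MiniCoopR-GFP, where no array was above the random probes. These calls lay close to the threshold: over 23 alternatives pank1a passed in 4, met in 5 and enpp4 in 6. None of them passed with the chip series as a block or without any 1 of the MiniCoopR-GFP arrays. All 23 kept the sign, but those that only leave out arrays could not turn it, since the groups do not overlap. For these 3 genes, and for every one of the 70 target sequences called, the 4 values of one group lay outside the range of the other.

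Over all 37157 target sequences, limma called 18 higher and 52 lower in MiniCoopR-SETDB1 at an adjusted p under 0.05. The fitted changes of these 70 ran from 2.04-fold to 9.57-fold, with a median of 3.01. In 4 of them every MiniCoopR-GFP array, and in 1 every MiniCoopR-SETDB1 array, was not above the random probes. The remaining 67 are transcripts that the files do not pair with a gene symbol. The transcript ENSDART00000076733 fell by 3.26 ± 0.25 on the log2 scale (SE, n = 4 per group, limma adjusted p = 0.0142), and OTTDART00000023555 fell by 2.08 ± 0.15 with the same adjusted p. OTTDART00000024146 rose by 2.51 ± 0.24 (SE, n = 4 per group, limma adjusted p = 0.0330), and ENSDART00000078015 was at least 1.95-fold higher (limma adjusted p = 0.0440).

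The groups did not overlap for 8.36% of all target sequences, 936 higher and 2170 lower, where chance gives 2.86% as a mean over groupings. Target sequences are not independent, and single groupings can lie well above that mean. Of the 35 splits of the 8 arrays into 4 and 4, the real one had 3106 without overlap and the highest of the others 2179. The balance between higher and lower depended on the scaling. With each array scaled to its 75th percentile, 2 were called higher and 12 lower, 493 were higher and 3918 lower without overlap, and the median of all target sequences lay at -0.26. Relative to that median 1 was called higher and 1 lower, and of the target sequences without overlap 1507 were higher and 1183 lower. Cyclic loess called 0 higher and 2 lower, and left 1132 higher and 1723 lower without overlap. The deposited value table called 11 higher and 14 lower. MiniCoopR-SETDB1 replicate 2 stood apart from all other arrays, and without it 193 were called higher and 238 lower, among them all 70. With the random probe level as a covariate limma called 0 target sequences, with 3179 at an unadjusted p under 0.05, against 5042 without it. Calls fell to 0 without MiniCoopR-GFP replicate 1, 3 or 4, with 4305, 3794 and 5094 at an unadjusted p under 0.05, and to 15, 3, 7 and 5 without MiniCoopR-GFP replicate 2 and MiniCoopR-SETDB1 replicates 1, 3 and 4. With the chip series as a block the count was 0, with 4741 at an unadjusted p under 0.05. It was 0 within the main series and 0 outside it, with 3181 and 3176.

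**Figure D1:**
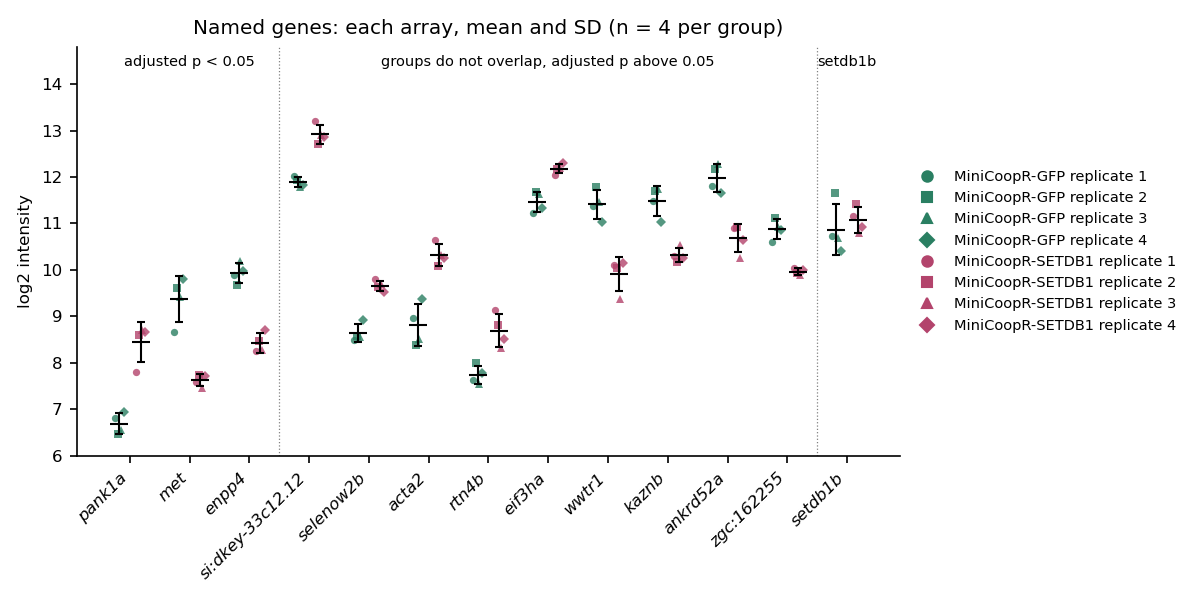
Log2 intensity (y axis) of 13 named genes (x axis) on each array, with replicates as symbols, MiniCoopR-GFP in green and MiniCoopR-SETDB1 in red, and black bars for the mean and SD of 4 arrays. The groups do not overlap for the first 12 genes, of which pank1a, met and enpp4 have an adjusted p under 0.05, and they overlap for setdb1b.

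The other named genes whose groups did not overlap had adjusted p-values above the threshold. Those higher in MiniCoopR-SETDB1 included acta2, smooth muscle actin, at a log2 difference of 1.51 ± 0.25 (SE, n = 4 per group, limma adjusted p = 0.0643). The uncharacterised gene si:dkey-33c12.12 differed by 1.04 ± 0.16 and the selenoprotein W gene selenow2b by 1.02 ± 0.16, both with an adjusted p of 0.0551. The reticulon gene rtn4b, whose protein shapes the endoplasmic reticulum, differed by 0.96 ± 0.21, and eif3ha, a subunit of translation initiation factor eIF3, by 0.71 ± 0.16. Of those lower, wwtr1, which encodes the Hippo pathway coactivator TAZ, differed by -1.50 ± 0.24 (SE, n = 4 per group, limma adjusted p = 0.0570). The kazrin gene kaznb differed by -1.17 ± 0.20, the protein phosphatase regulator ankrd52a by -1.29 ± 0.22, and the uncharacterised zgc:162255 by -0.91 ± 0.16. Counted over the 2650 symbols alone, limma called 0 genes, with 341 at an unadjusted p under 0.05, 241 of them lower.

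The spread between tumours was larger among MiniCoopR-SETDB1 melanomas. Across target sequences, which are not independent replicates, pairs of MiniCoopR-GFP arrays correlated at a mean r of 0.955 ± 0.00723 (SD of 6 pairs), and pairs of MiniCoopR-SETDB1 arrays at 0.899 ± 0.0375. Without MiniCoopR-SETDB1 replicate 2 the latter mean was 0.932, and between the groups it was 0.912. The first principal component, with 31.0% of the variance, placed MiniCoopR-SETDB1 replicate 2 at 163 and all other arrays between -31.2 and -14.8. The second, with 22.5%, placed the MiniCoopR-GFP arrays between -64.4 and -20.1 and MiniCoopR-SETDB1 replicates 1, 3 and 4 between 57.1 and 68.4. On MiniCoopR-SETDB1 replicate 2, 40 named genes had an intensity over 4-fold above every other array, against 12 at most on any other. The pluripotency factor nanog reached 14.12 on the log2 scale there and at most 7.34 elsewhere, the egg coat gene zp2.2 15.24 against at most 8.80, and the oocyte histone mRNA binding gene slbp2 14.01 against at most 7.47. Neither nanog nor slbp2 was above the random probes on any other array. The melanosome cation exchanger slc24a5 lay at 7.60 there and at 11.23 or more on the other arrays. These genes were chosen after their values were seen.

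**Figure D2:**
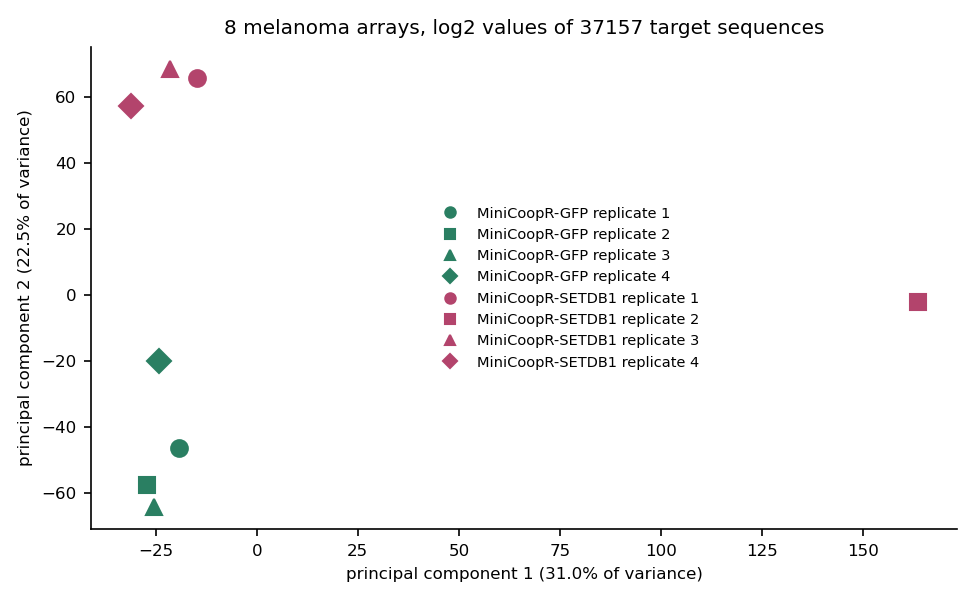
First and second principal component (axes in component units) of the log2 values of 37157 target sequences on 8 arrays, MiniCoopR-GFP in green and MiniCoopR-SETDB1 in red. The first component places MiniCoopR-SETDB1 replicate 2 at 163, and the second parts the MiniCoopR-GFP arrays from MiniCoopR-SETDB1 replicates 1, 3 and 4.

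Of the 22 gene lists tested, the skeletal muscle and the cell cycle list rose in MiniCoopR-SETDB1 melanomas by camera with a preset correlation. With an estimated correlation neither passed, with adjusted p = 0.614 for muscle and adjusted p = 0.610 for the cell cycle. As many lists were called in 7 of the 35 splits of the 8 arrays, the real one included. Of 18 measured muscle genes 15 were higher, with a median log2 difference of 0.58 (camera adjusted p = 8.66e-05, and 0.369 by fry). The gene mybpc2b, a myosin binding protein of fast muscle, differed by 2.44 ± 0.70 (SE, n = 4 per group, limma adjusted p = 0.193), and ampd1, muscle AMP deaminase, by 2.14 ± 0.62 (adjusted p = 0.196). No member passed the threshold over all target sequences, and 0 did adjusted over the list alone. The list mean was 9.33, 9.64 and 9.53 in MiniCoopR-SETDB1 replicates 1, 3 and 4, 8.19 in replicate 2, and 8.10 to 8.70 in MiniCoopR-GFP (exact permutation p = 0.114, two-sided, n = 4 per group). Without replicate 2, 5 muscle genes passed the threshold: ampd1, mybpc2b, the glycogen phosphorylase pygma at 2.23 ± 0.24, the actin acta1b at 1.79 ± 0.29 and the troponin tnni2a.3 at 3.11 ± 0.51 (SE, limma adjusted p from 0.0308 to 0.0459). The shift of the list mean was 0.79, and 0.66 with the chip series as a block. It was 0.59 within the main series, where camera's adjusted p was 0.0518, and 0.79 outside it, where MiniCoopR-GFP had 1 array. With the random probe level as a covariate it was 1.12.

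All 4 measured cell cycle genes were higher, with a median of 1.04 (camera adjusted p = 0.00160; adjusted p = 0.610 with an estimated correlation and 0.225 by fry). The replicative helicase subunit mcm5 differed by 1.0 ± 0.23 (SE, n = 4 per group, limma adjusted p = 0.123) and cyclin A2, ccna2, by 1.38 ± 0.50 (adjusted p = 0.283). Adjusted over the list alone 2 of the 4 passed. The list mean was 11.63 ± 0.69 (SD, n = 4) in MiniCoopR-GFP and 12.69 ± 0.54 (SD, n = 4) in MiniCoopR-SETDB1 (exact permutation p = 0.0571, two-sided). MiniCoopR-GFP replicate 2 was lowest at 10.59. It also had the lowest slope along the target, 0.298, and the lowest share of target sequences above the random probes, 61.2%, of the 8 arrays. Without it camera's adjusted p was 0.00830. Without MiniCoopR-SETDB1 replicate 2 it was 0.0246. The list's shift of 1.06 became 1.16 with the chip series as a block, and 0.55 within the main series, where camera's adjusted p was 0.0908. Outside the main series the shift was 2.27, but MiniCoopR-GFP replicate 2 was the only control array there. The value with the block draws on that array too. The random probe level, which differs between the groups, as a covariate left a shift of 0.81 and a camera adjusted p of 0.216.

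**Figure D3:**
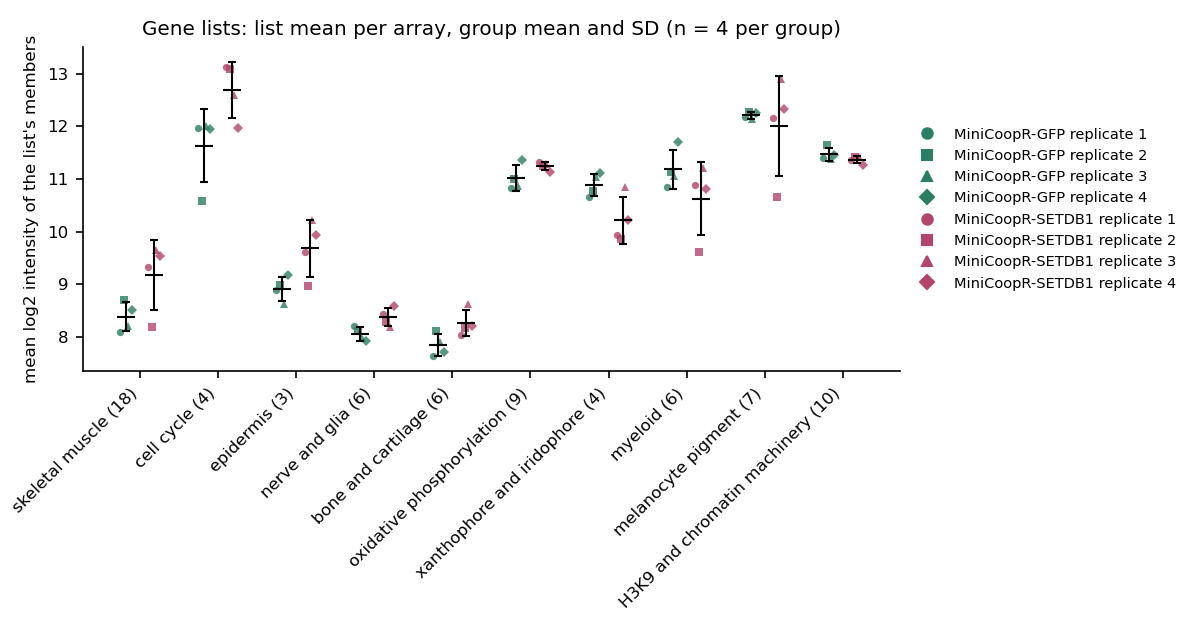
Mean log2 intensity of the members of 10 gene lists (y axis; measured members in parentheses on the x axis) on each array, MiniCoopR-GFP in green and MiniCoopR-SETDB1 in red, and black bars for the mean and SD of 4 arrays. The muscle list mean lies between 9.33 and 9.64 on MiniCoopR-SETDB1 replicates 1, 3 and 4 and at 8.19 on replicate 2.

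Markers of the other cell types did not pass camera's threshold. The 3 epidermis genes were all higher, with an adjusted p of 0.0572, which was under the threshold in 8 of the alternatives, the deposited value table among them (adjusted p = 0.610 with an estimated correlation and 0.225 by fry). Of these genes agr1 differed by 1.15 ± 0.31 (SE, n = 4 per group, limma adjusted p = 0.161). Of 6 nerve and glia genes 5 were higher (camera adjusted p = 0.169), with fabp7a, a glial fatty acid binding protein, at 0.90 ± 0.36. Of 4 xanthophore and iridophore genes 3 were lower (0.247), among them gmps, of guanine nucleotide synthesis, at -0.76 ± 0.23 and csf1ra, also on the myeloid list, at -1.49 ± 0.68. Over 23 alternatives gmps ran from -1.18 to -0.34 and csf1ra from -1.94 to -0.275. Of 6 myeloid genes 4 were lower (0.247), and runx1, a blood cell transcription factor, differed by -0.97 ± 0.21 (SE, n = 4 per group, limma adjusted p = 0.105). Of 6 bone and cartilage genes 4 were higher (0.60), and the cartilage matrix gene matn3a, 1 of the 2 lower, differed by -0.45 ± 0.13. Of 6 fibroblast and matrix genes 4 were lower (0.878), with the matrix gene fbln1 at -1.49 ± 0.46, while acta2, also a member, was higher, at 1.51 ± 0.25. Adjusted over the list alone, agr1 and acta2 passed as higher and gmps, runx1 and fbln1 as lower. Adjusted p-values were 0.844 for 4 erythrocyte genes, and 0.878 for 5 lymphocyte and for 8 endothelial genes. The fibroblast list had a median of -0.11 and a mean of -0.07, while the direction camera gave was a rise.

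Melanocyte pigment genes gave no difference past the threshold. Of 7 measured, 4 were higher and 3 lower (camera adjusted p = 0.992). The rule took atp7a, at -0.61 ± 0.38 (SE, n = 4 per group, limma adjusted p = 0.539), and slc24a5, at -0.85 ± 1.37 (adjusted p = 0.828). With 1 array left out slc24a5 ran from -1.96 to 0.52. The melanin synthesis enzyme dct, which the rule did not take, differed by 0.07 ± 0.27 (SE, n = 4 per group, limma adjusted p = 0.930). The list had a median of 0.02 and a mean of -0.20. The list mean was 12.21 ± 0.06 (SD, n = 4) in MiniCoopR-GFP and 12.01 ± 0.96 (SD, n = 4) in MiniCoopR-SETDB1, where replicate 2 was lowest at 10.66 and replicate 3 highest at 12.90. Replicates 1 and 4 lay at 12.15 and 12.33, and the MiniCoopR-GFP arrays between 12.14 and 12.27. The negative mean difference thus rests on replicate 2. Of 4 neural crest and early pigment progenitor genes 2 were lower (0.878), and tfap2e, a melanocyte AP-2 factor, differed by -0.65 ± 0.19 and passed when adjusted over the list alone.

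The transgene itself was not resolved. The setdb1b target sequence of the zebrafish gene was detected on all 8 arrays and differed by 0.21 ± 0.29 (SE, n = 4 per group, limma adjusted p = 0.798; exact permutation p = 0.514, two-sided). The setdb1b difference was 0.57 within the main chip series and -0.69 outside it, where MiniCoopR-GFP had 1 array, and 0.12 with the series as a block. It ran from 0.05 without MiniCoopR-GFP replicate 4 to 0.47 without replicate 2 of that group, was 0.09 without MiniCoopR-SETDB1 replicate 2, and was -0.07 with the random probe level as a covariate. The species of the delivered SETDB1 sequence is not given in the sources used here, so this target checks the labels only if the vector carries a sequence it matches. Of 10 measured H3K9 and chromatin machinery genes 6 were lower (camera adjusted p = 0.992), with the Polycomb gene cbx7a at -0.80 ± 0.43. The cbx7a difference ran from -2.33 to 0.06 over 23 alternatives and kept its sign in 22. Only 1 of 49 HOX genes was measured under a symbol, hoxc13b, which lay between 6.96 and 7.81 on 7 arrays and at 12.96 on MiniCoopR-SETDB1 replicate 3. Its difference was 1.11 ± 1.21 (SE, n = 4 per group, limma adjusted p = 0.734), -0.31 without that array and -0.28 within the main chip series. The list was chosen knowing the study's interest in HOX genes, and the single gene does not test it. Of 16 other homeobox genes 9 were lower (camera adjusted p = 0.896), with meis3 at -1.13 ± 0.45. The homeobox and chromatin lists had means of -0.05 and -0.10, while the direction camera gave was a rise.

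The remaining lists also stayed above the threshold. Of 9 oxidative phosphorylation genes 6 were higher (camera adjusted p = 0.227), and 2 passed when adjusted over the list alone, the ATP synthase subunits atp5mc1 at 0.93 ± 0.24 (SE, n = 4 per group) and atp5f1b at 0.54 ± 0.15. All 3 interferon and antigen presentation genes were lower (0.411), with the RNA sensing cofactor trim25 at -0.79 ± 0.25, which passed when adjusted over the list alone. Of 5 ribosomal protein genes 4 were higher (0.844). The adjusted p was 0.878 for 3 p53 pathway and senescence genes, for 3 MAPK output genes, for 8 Wnt pathway targets and for 3 stress and immediate early genes.

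**Figure D4:**
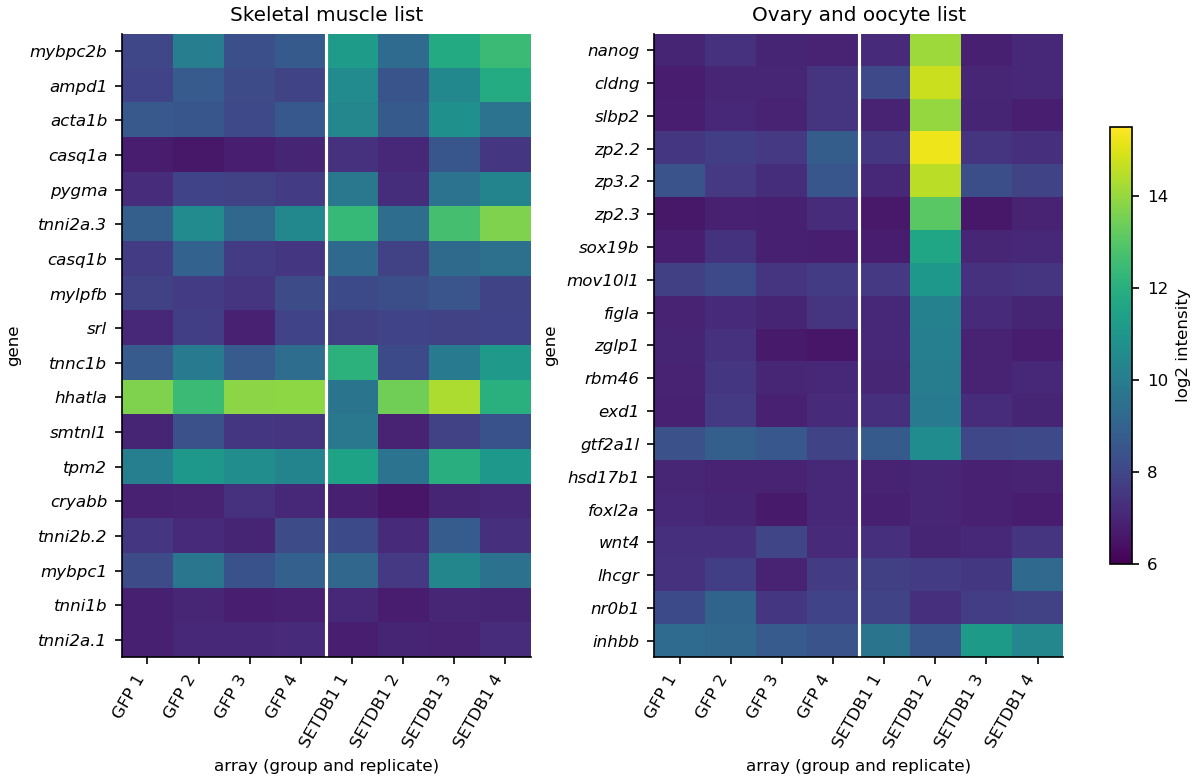
Log2 intensity (colour) of each measured gene (y axis) of the skeletal muscle list and of an ovary and oocyte list, whose genes were chosen after 13 of their values were seen, on 8 arrays (x axis; the white line parts the groups). Muscle genes such as mybpc2b are brightest on MiniCoopR-SETDB1 replicates 1, 3 and 4, and 13 genes of the other list, nanog at 14.12 first, are brightest on replicate 2.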

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

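The tests of the lower share over splits, of ovary tissue, of a swap and of muscle tissue below were chosen after the result was seen, and the others before. Of 170 groups of 4 values checked, 7 had 1 array far from the other 3, where chance gives 8.5. Among MiniCoopR-SETDB1 arrays, hoxc13b lay at 12.96 on replicate 3 against 6.96 to 7.81, and wwtr1 at 9.38 on the same array against 10.03 to 10.15. On replicate 1, pank1a lay at 7.80 against 8.59 to 8.71, and tfap2e at 12.85 against 12.50 to 12.54. The p53 pathway and senescence list mean was 10.47 on replicate 2 against 9.41 to 9.58. Among MiniCoopR-GFP arrays, replicate 2 had mcm5 at 10.43 against 11.15 to 11.25 and a cell cycle list mean of 10.59 against 11.95 to 12.01.

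More target sequences were lower than higher in MiniCoopR-SETDB1. For the number of calls chance is argued against, but only over splits that take no account of the chip series. Of the 35 splits of the 8 arrays 1, the real one, gave as many, 70 against at most 2. That is the lowest share these splits can give, so chance is not excluded. With the chip series as a block limma called 0, with 4741 at an unadjusted p under 0.05. For the direction chance is not argued against, since 3 of the 35 splits had as large a share one way among target sequences without overlap, 69.9% in the real one and 71.7% in the highest of the others. Of the non-overlapping target sequences above the random probes on all 8 arrays 74.0% were lower. As the test was set, this counted against the brighter background of the control arrays as the whole cause. It cannot decide that, since a split other than the real one reached 71.7% one way over all target sequences. The random probe level also parts the groups fully, so it cannot be told apart from the group. As a covariate it left 0 calls, with 3179 at an unadjusted p under 0.05, against 5042 without it. The scaling between arrays stays open, because cyclic loess left 60.4% lower and the 75th percentile 88.8%. Centred on its median the latter became 44.0%, a step that itself moves this balance. A single array stays open as well, since without MiniCoopR-SETDB1 replicate 2 the share was 60.3%. The shares of 60.4% and 60.3% lay above the 60% set beforehand as the bound against scaling and a single array. The excess was less than an error computed as if target sequences were independent, a margin added after the values were seen. Target sequences share the same arrays, so this is not the error of the comparison, and the shares decide neither explanation. An effect of SETDB1 itself was not tested apart from these explanations.

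MiniCoopR-SETDB1 replicate 2 stood apart from the other arrays. A poor hybridisation is argued against by a probe residual 0.579 times the highest of the other 7, and degraded RNA by a slope along the target of 0.49, inside their range of 0.30 to 0.67. No preset cell type list reached above the highest other array, the closest being nerve and glia at -0.31. The mean correlation of replicate 2 with the MiniCoopR-GFP arrays, 0.876, was below those of the other MiniCoopR-SETDB1 arrays, 0.921 to 0.928. As the test was set this counted against a swap between the groups. It cannot decide that, since replicate 2 correlated poorly with every array, at 0.883 or less. Its mean correlation with its own group was 0.865. A candidate explanation is ovary tissue or oocytes in the tumour piece, since all 13 ovary and oocyte list genes that prompted the idea were highest there. Of the 6 list members not seen before, 0% were highest on it, which as the test was first set counted against ovary tissue; it was taken as undecided only after that value was seen, because these are genes of ovarian somatic cells or hormones, none an oocyte gene, and only 2 of them, inhbb and nr0b1, were above the random probes on 4 or more arrays, and a tumour with oocyte genes switched on was not tested.

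The skeletal muscle list was higher in MiniCoopR-SETDB1 melanomas. A single array is argued against, since the smallest difference in the list mean with 1 array left out, MiniCoopR-SETDB1 replicate 3, kept 80.1% of the whole. Muscle tissue in the tumour piece may account for it but was not decided: of the 15 muscle genes above the random probes on some array 93.3% were higher, which restates the shift that prompted the idea and cannot part such tissue from muscle genes switched on in tumour cells. The list mean was 9.33 to 9.64 on replicates 1, 3 and 4 and 8.19 on replicate 2, inside the range of the MiniCoopR-GFP arrays, and the fast troponin gene tnni2a.3 differed by 2.23 ± 0.87, while hhatla, the exception among the 15, differed by -1.11 ± 0.92 (SE, n = 4 per group). Deeper growth of these tumours was not tested, and camera's count of 2 lists was reached by 7 of the 35 splits, with 2 the highest of the others, so chance is not excluded for it.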

How the results depend on the processing

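The reprocessing without MiniCoopR-SETDB1 replicate 2 and the random probe covariate were chosen after seeing the data, and the other alternatives before. The count of 70 target sequences (18 higher, 52 lower) kept its order of more lower than higher wherever any were called, except with the 75th percentile relative to its median (1 higher, 1 lower). It did not keep its size, and why the size moved was not tested. Offset 0 gave 18 (6 higher, 12 lower), as did the filter on dim sequences, 18 (6 and 12). Without background correction 79 of 99 were lower. The 75th percentile gave 14 (2 and 12), cyclic loess 2 (0 and 2), the deposited values 25 (11 and 14), and a trended robust variance 4 (1 and 3). Array weights gave 334 (75 and 259), an adjusted p under 0.1 gave 499 (100 and 399), and the 7 arrays processed again 264 (115 and 149). The chip series as a block, the main chip series alone, the other chips alone, gene symbols as the unit and the random probe covariate each gave 0 (0 higher, 0 lower), with 4741, 3181, 3176, 341 and 3179 at an unadjusted p under 0.05. Leaving out 1 array gave 0 to 431 (0 to 193 higher, 0 to 238 lower). The replicate numbers showed no sign of pairing the tumours, though a weak pairing is not excluded. Same-numbered arrays deviated together at r = 0.0165, 0.000852, -0.0989 and -0.102, against -0.150 to 0.226 for arrays with different numbers. The replicate block gave 0 (0 higher, 0 lower), with 4401 at an unadjusted p under 0.05. Without overlap, the 75th percentile gave 493 higher and 3918 lower. The skeletal muscle list passed camera's threshold except in the main chip series (adjusted p = 0.0518), with an estimated correlation (0.614) and by fry (0.369). The cell cycle list passed except in that series (0.0908), with the random probe covariate (0.216), with an estimated correlation (0.610) and by fry (0.225). Leaving out 1 array moved these adjusted p-values from 8.44e-09 to 0.00225 and from 0.000366 to 0.0246. Lists called numbered 0 in the main chip series, 1 with the covariate, 0 with an estimated correlation and by fry, and 2 or 3 in the other fits. Of 509 list values above the threshold in both fits 63 changed sign, and of 1193 such values of named genes 28 did. The 12 genes without overlap kept their sign in all 23 alternatives, with pank1a past the threshold in 4, met in 5 and enpp4 in 6. As they were chosen for groups without overlap, leaving out arrays, the chip subsets and the variance model could not turn the sign. Those alternatives are no test of it. The median signal over the random probes, 2.4 ± 0.45 (SD, n = 4) in MiniCoopR-GFP and 3.56 ± 0.66 in MiniCoopR-SETDB1, limits what dim sequences can show.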

Other observations

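The further gene lists were chosen after the data had been examined, and the test of TAZ target genes was fixed before its members' values were seen. A wider list of DNA replication and mitosis genes, which holds all 4 measured members of the cell cycle list, was higher in MiniCoopR-SETDB1 melanomas: 16 of 18 were higher, with a median log2 difference of 0.81 (camera adjusted p = 3.08e-06 over 16 lists; adjusted p = 0.384 with an estimated correlation). The mitotic transcription factor foxm1 differed by 1.13 ± 0.40 (SE, n = 4 per group, limma adjusted p = 0.273), the replication origin factor mcm10 by 1.16 ± 0.45, and the augmin subunit haus6, which builds spindle microtubules, by 0.98 ± 0.35. Without MiniCoopR-SETDB1 replicate 2 the list's adjusted p was 0.00134 and the median 0.59, with foxm1 at 0.92, mcm10 at 0.67 and haus6 at 0.72. Of 13 mitochondrial ribosome genes 8 were higher (camera adjusted p = 0.0265; 0.384 with an estimated correlation; 0.173 without replicate 2), with mrpl20 at 0.60 ± 0.18. Of 19 ovary and oocyte genes 15 were higher (camera adjusted p = 0.0265; 0.681 with an estimated correlation), and without replicate 2 the adjusted p was 0.986. The 13 other lists with at least 3 members had adjusted p-values from 0.103 to 0.998.

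Leaving out MiniCoopR-SETDB1 replicate 2, limma called 24 named genes, 14 higher and 10 lower, among 431 target sequences. Of the 35 splits of these 7 arrays 1, the real one, gave as many calls, and the highest of the others gave 12, with no account taken of the chip series. That is the lowest share these splits can give, and the array left out was the one that stood apart from its group. Chance is therefore not excluded. Beside muscle genes, the genes named next were chosen here after their values were seen. The globin X gene xgb had a log2 difference of -3.08 ± 0.44 (SE, limma adjusted p = 0.0327). The choline transporter gene slc44a4 differed by -2.0 ± 0.35 (adjusted p = 0.0491) and the transcription factor gene klf13 by 2.03 ± 0.35 (adjusted p = 0.0488). With MiniCoopR-SETDB1 replicate 2 kept, none of xgb, slc44a4 and klf13 passed the threshold. The differences were then -2.57 for xgb (limma adjusted p = 0.114), -1.57 for slc44a4 (adjusted p = 0.211) and 1.49 for klf13 (adjusted p = 0.292).

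The lower wwtr1 transcript could be accompanied by lower target genes of YAP and TAZ. Among 7 such genes whose values had not been seen, camera gave an unadjusted p of 0.602 with the direction of a rise. Such a result had been set beforehand as one against a common fall, but 4 of the 7 were lower and 3 higher, with a median of -0.06, so it decides nothing and the question stays open. The largest values were cited2 at 1.1 ± 0.56 and amotl2a at -0.80 ± 0.40 (SE, n = 4 per group). The list members cav1 at -1.18 ± 0.24, nf2b at -0.83 ± 0.18 and vgll4b at -0.94 ± 0.21 were left out of that test because their values had been seen. With them, 7 of 10 genes were lower, with a median of -0.41 (camera unadjusted p = 0.0872, adjusted p = 0.199 over 16 lists and adjusted p = 0.384 with an estimated correlation). As these members were known to be lower, the figures for all 10 are no evidence of a common fall. Without MiniCoopR-SETDB1 replicate 2, 5 of the 10 were higher, with a median of -0.25 (camera unadjusted p = 0.219).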
